A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

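Messenger RNA of the budding yeast Saccharomyces cerevisiae was sequenced in 2 libraries, 1 from strain CY2706, which carries wild-type TRA1, and 1 from strain CY3003, which carries the tra1-L3733A allele. Per the labels' protocols, both strains were grown in rich medium (YP) with 2% glucose at 30 °C to an A600 of 2.0, total RNA was taken from whole cells broken with glass beads, and every RNA sample had an integrity number above 8.9. Each library was sequenced on 1 lane of an Illumina Genome Analyzer II as 35-nucleotide reads, which gave 13014880 reads for the TRA1 library and 11156078 for the tra1-L3733A library per the labels' protocols.

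Novoalign, a read aligner, is the tool named, per the submitters' processing notes. Its version, the genome build and the annotation release are not given in the sources used here. The deposited files hold raw read counts for 6603 open reading frames (ORFs), each with its name, chromosome, start and end, and with counts in columns headed fr and rr, per the file headers. These columns are not defined in the sources used here and were taken as the forward and reverse read directions. A further deposited column of coverage gives reads per base. It equals the sum of both read directions divided by the ORF's span in all 13206 entries of the 2 files, to a tolerance of 1e-06, and it was not used beyond that check. The deposited counts are not scaled to library size. The start of 918 of the 5918 ORFs that matched a coding gene of the R64 reference by identifier was the same as in R64, so the files follow another build or annotation, and no coordinate of one was combined with the other. Coordinates below are the files' own unless R64 is named. Whether the library kit kept strand is not given in the sources used here. The forward direction held 49.2% of the counts in the TRA1 library and 49.4% in the tra1-L3733A library. That share does not tell whether strand was kept, since genes lie on both strands. In the TRA1 library the TRA1 ORF had 5727 forward and 6308 reverse reads, LEU1 had 14431 and 14612, and PHO84 had 8341 and 8414. At least 50 reads per direction and library were found for 5136 ORFs. If the columns are read directions, these values argue against strand having been kept, for these ORFs. Some short ORFs were uneven, such as DDR2 with 102 and 1246 reads and CUP1-2 with 739 and 2390, each of span 185. The directions were summed, and reads of an ORF and of an ORF opposite to it are not separated here. A total of 1244 ORFs overlap another listed ORF by 1 base or more, and a read in the shared part may count for both. The 28 mitochondrial ORFs are listed at 0 in both libraries.

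Both read directions were summed here. The sums were 11564964 counts for TRA1 and 9970836 for tra1-L3733A. Library sizes were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 (R 4.3.3), with factors of 1.035 for TRA1 and 0.967 for tra1-L3733A, and abundances are counts scaled to 1e6 (CPM) of that size. With 1 library per strain, edgeR's quasi-likelihood test has no replicates to estimate a spread from, so no p-value is given for any gene. In its place, the ratio of tra1-L3733A to TRA1 was given a 95% exact (Clopper-Pearson) counting interval. An ORF was called higher or lower by a size rule: at least 20 reads summed over both libraries, a ratio of at least 1.5 either way, and an interval that excludes 1. These intervals cover counting error only. They do not cover the spread between cultures, and reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 reads, which is 0.259 CPM of the unscaled total in the TRA1 library and 0.301 CPM in the tra1-L3733A library. Log2 ratios used 0.5 reads added to both counts.

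There were 37 gene lists, fixed with the size rule and the rules below before the data were examined. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, matched on mean abundance in 20 bins. The random lists were drawn from all tested ORFs of a bin, members of that list and of the other lists included. That percentile describes these 2 libraries and is not a test across cultures. If genes moved independently of each other, 1.85 of 37 lists would fall outside the central 95%. Genes of a list may move together and some lists share genes, so this number is not the chance expectation for these lists. With 1 library per strain that expectation could not be estimated. Members were found by the files' names or, for older names, through the R64 gene table. All listed members were found. Genes with the element TATAWAWR between 50 and 200 bp upstream of the start codon on the coding strand, and genes within 20 kb of a chromosome end, were taken from R64 by identifier and treated in the same way. The genes named are TRA1, the 12 higher and the 12 lower ORFs whose interval bound nearest to 1 lies farthest from it, and from each list the 2 to 4 members with the largest such bound or, where none passed the size rule, the 2 with the most reads. Genes named outside this rule are said to be so.

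On simulated counts drawn from the means and sizes of these libraries for 6254 ORFs, the size rule found 98.0% of 50 genes raised 2-fold, 98.0% of 50 lowered 2-fold, 100.0% of 50 raised 3-fold and 96.0% of 50 lowered 3-fold. It called 18 of 6057 unchanged genes, and 95.3% of the intervals held the true ratio. The simulation holds counting error alone.

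The alternatives were scaling by total counts, by DESeq2 1.42.0 size factors and by the stated lane reads; a filter of 1 or 100 reads; removal of the median trend over 10 bins of ORF span or of GC content; a size rule of 2 or 1.3; and an interval widened by an assumed coefficient of variation of 0.1 per library. GC content was known for 91.0% of the tested ORFs. Counts of 1 read direction, and ORFs that overlap no other and match R64, were added after seeing the data. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.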

Results

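Transcript abundance was measured in 2 yeast libraries, 1 from a strain with wild-type TRA1 and 1 from a strain with the tra1-L3733A allele. Tra1 is a very large protein of the phosphatidylinositol 3-kinase-related kinase (PIKK) family and a subunit shared by the SAGA and NuA4 histone acetyltransferase complexes. The series' title and design text name a single comparison, which asks how gene expression differs between the strain with the substitution and the strain with the wild-type gene. The TRA1 library held 11564964 counts in 6603 listed ORFs and the tra1-L3733A library 9970836, with a median of 481 reads per ORF for TRA1 and 373 for tra1-L3733A. Reads were found for 6512 ORFs in the TRA1 library and 6507 in the tra1-L3733A library, and 69 ORFs had 0 reads in both. The 20 most abundant ORFs held 22.03% of the TRA1 counts and 25.53% of the tra1-L3733A counts. There was 1 library per strain, so no difference below has a replicate check, and each compares these libraries, not the genotypes.

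The TRA1 transcript itself was lower in the tra1-L3733A library. TRA1 (YHR099W, chromosome VIII, 302764 to 313998 in the files' coordinates) had 12035 reads in the TRA1 library and 5102 in the tra1-L3733A library, or 1006 against 529 CPM, a ratio of 0.526 (95% counting interval 0.509 to 0.544) and a log2 ratio of -0.93. In the R64 annotation TRA1 is a single-exon gene on the forward strand at VIII, 302761 to 313995, that encodes 3744 residues. The L3733A substitution changes the codon TTA at positions 313957 to 313959 (R64), 11 residues from the C terminus. A point mutation need not alter the abundance of its mRNA, so this ratio does not check the labels.

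SPL2, PHO84 and other phosphate starvation genes, LEU1, OAC1 and LYS9 were among the ORFs farthest below 1 in tra1-L3733A relative to TRA1, and HSP26, PIR3, PUT4 and MEP2 were among those farthest above 1. Of 6248 ORFs with at least 20 reads, 175 (2.80%) passed the size rule as higher in the tra1-L3733A library, 341 (5.46%) as lower and 5732 as neither. At least 2-fold differences were found for 20 higher and 57 lower ORFs. With scaling by total counts the split was 91 higher and 515 lower, and with scaling by lane reads it was 98 higher and 500 lower, so the share of higher calls went from 33.9% to 16.4% or less. Across ORFs, which are not independent replicates, the log2 abundances of the libraries had a Pearson correlation of 0.987, and the SD of the log2 ratio was 0.35. Of the ORFs that passed, 52 of 175 higher and 53 of 341 lower ones overlap another listed ORF, against 1244 of all 6603. The share was thus larger among higher than among lower calls. Without overlapping or unmatched ORFs, an alternative chosen after seeing the data, 120 were higher and 284 lower of 5038 tested.

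**Figure D1:**
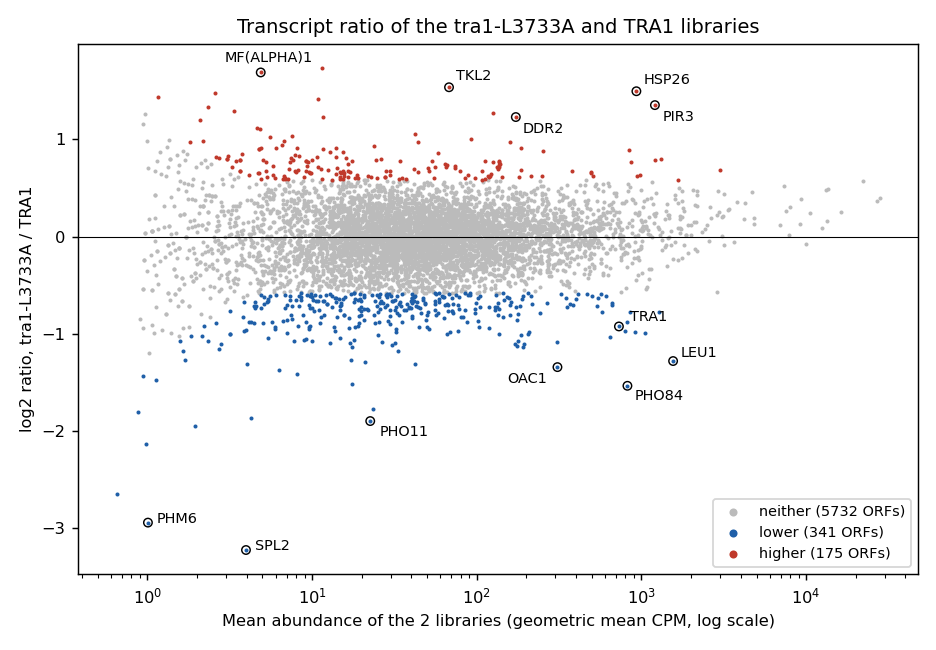
Log2 ratio of tra1-L3733A to TRA1 for each of the 6248 tested ORFs against the geometric mean abundance of both libraries in CPM on a log scale. Red points (175) were higher and blue points (341) lower by the size rule, gray points (5732) were neither, and circled ORFs are named. Of the circled ORFs, SPL2 lies lowest, at -3.23, and PIR3 is at 1.35.

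The ORFs that stood farthest above 1 included HSP26 (YBR072W, II, 382027 to 382671), a small heat shock protein, with 6634 reads for TRA1 and 15083 for tra1-L3733A and a ratio of 2.82 (2.74 to 2.91). TKL2, a minor transketolase, had a ratio of 2.91 (2.61 to 3.24), and YBR116C, which overlaps it and has no match in R64, had 2.69 (2.05 to 3.55), so their reads cannot be separated. PIR3 (YKL163W, XI, 144406 to 145383), a cell wall glycoprotein, was at 2.56 (2.49 to 2.62). FMP16 was at 3.34 (2.55 to 4.42) on 75 and 202 reads, YHR033W at 2.42 (2.24 to 2.62) and GRE1 at 2.35 (1.81 to 3.06). HPA3, which overlaps YEL067C, was at 2.01 (1.83 to 2.20). The stress gene DDR2 was at 2.35 (2.20 to 2.51) on all reads, but at 0.987 (0.728 to 1.33) on its 102 and 81 forward reads and at 2.46 (2.30 to 2.64) on its 1246 and 2468 reverse reads, so its call rests on 1 read direction.

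The ORFs that stood farthest below 1 outside the phosphate genes included OAC1 (YKL120W, XI, 216988 to 217962), a mitochondrial carrier of oxaloacetate, at 0.394 (0.373 to 0.415). LEU1 (YGL009C, VII, 476318 to 478657), the isopropylmalate isomerase of leucine synthesis, was at 0.411 (0.402 to 0.421) on 29043 and 9617 reads. LYS9, an enzyme of lysine synthesis, was at 0.454 (0.425 to 0.484). MDM35, a protein of the mitochondrial intermembrane space, was at 0.347 (0.275 to 0.435). YDR379C-A was at 0.269 (0.159 to 0.434) on 97 and 21 reads, and YNL155W at 0.403 (0.349 to 0.464). The copper metallothionein CUP1-2 was at 0.456 (0.426 to 0.488), an uncertain value since CUP1-1 is a near-identical copy and CUP1-2 also overlaps YHR054W-A.

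Phosphate starvation genes were lower in the tra1-L3733A library as a group. Of 15 genes, 11 were lower by the size rule and 0 were higher, and all 15 log2 ratios lay below 0. SPL2, a regulator of phosphate transport, had 145 reads for TRA1 and 12 for tra1-L3733A, a ratio of 0.103 (0.0519 to 0.185). PHO84 (YML123C, XIII, 24038 to 25801), the high-affinity phosphate transporter, had 16755 and 4649 reads and a ratio of 0.344 (0.333 to 0.356). The acid phosphatases PHO11 and PHO12 were at 0.267 (0.216 to 0.328) and 0.292 (0.238 to 0.356), but are near-identical copies whose reads may be assigned to either. PHM6 was at 0.113 (0.0221 to 0.360) on 33 and 3 reads. The list's median log2 ratio was -0.87, at percentile 0.0 of the matched random lists, whose central 95% ran from -0.20 to 0.19.

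**Figure D2:**
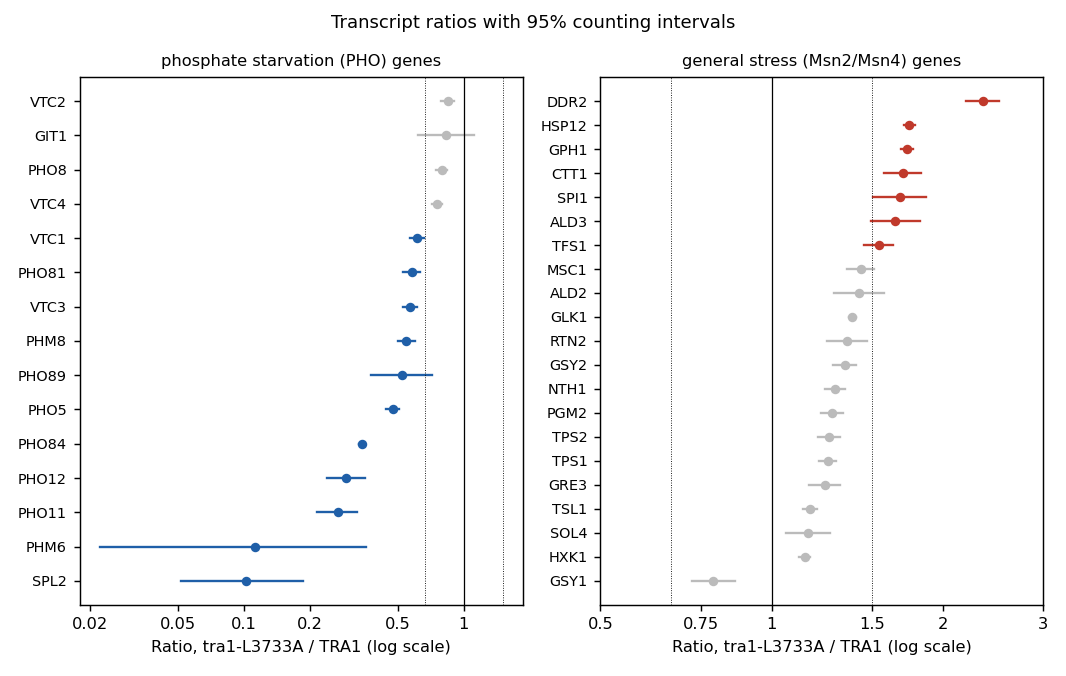
Ratio of tra1-L3733A to TRA1 (log axis) for each of 15 phosphate starvation genes (left) and 21 general stress genes (right), with 95% counting intervals as lines and dotted lines at the size rule of 1.5 either way. On the left 11 genes were lower (blue) and on the right 7 were higher (red).

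Cytosolic ribosomal protein genes were also lower as a group. Of 137, 23 were lower by the size rule, with ratios of 0.470 to 0.666, and 0 were higher. The number lower was 30 with scaling by total counts or lane reads, 19 with the length trend removed and 20 with the GC trend removed. In all, 108 log2 ratios lay below 0. The median was -0.22, at percentile 0.0, and the central 95% of the random lists ran from 0.01 to 0.10. RPL27B was at 0.470 (0.446 to 0.494), RPS22A at 0.489 (0.472 to 0.506), RPS23B at 0.503 (0.489 to 0.517) and RPS23A at 0.505 (0.490 to 0.520), though copies of a pair share sequence and their reads may be split between them. Together these genes held 10.4% (10.41 to 10.45%, exact binomial) of the TRA1 counts and 8.39% (8.37 to 8.41%) of the tra1-L3733A counts.

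Among 29 amino acid synthesis genes that are targets of the activator Gcn4, 6 were lower and 0 higher, against 7 lower with scaling by total counts or lane reads and 5 with the length or GC trend removed. LYS20, a homocitrate synthase, was at 0.464 (0.433 to 0.497), LYS1 at 0.498 (0.446 to 0.557) and HIS1 at 0.604 (0.576 to 0.633), beside LYS9. The median was -0.09, at percentile 1.1, and at 2.78 with the GC trend removed, which is inside the central 95%. By sign, 18 log2 ratios lay below 0 and 11 above. The lower genes LYS1, LYS9, LYS20 and LYS21, the last chosen after its values were seen, all belong to lysine synthesis. The other lower genes, HIS1 and HIS4, belong to histidine synthesis. HIS4, likewise chosen, was at 0.664 (0.633 to 0.697). Arginine synthesis genes, kept as a list of their own, were not lower, with a median of 0.12 at percentile 78.7. Of 6 measured auxotrophic marker genes, LYS2 at 0.638 (0.599 to 0.680) and TRP1 at 0.658 (0.599 to 0.722) were lower and 0 were higher, with a median of -0.34 at percentile 0.66. The TRP1 call was lost with the length or GC trend removed, and TRP1 overlaps YDR008C. HIS3, chosen after its values were seen, had 0 reads in both libraries, which allows up to 0.259 CPM for TRA1 and 0.301 for tra1-L3733A.

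General stress genes regulated by Msn2 and Msn4 were higher in the tra1-L3733A library as a group. Of 21 genes, 7 were higher and 0 lower, with a median of 0.44 at percentile 100. The count was 6 with scaling by total counts or lane reads, with the GC trend removed and without overlapping or unmatched ORFs. HSP12, a membrane-associated stress protein, was at 1.75 (1.71 to 1.79), the glycogen phosphorylase GPH1, which overlaps 2 other ORFs, at 1.73 (1.69 to 1.77) and the catalase CTT1 at 1.70 (1.58 to 1.83), beside DDR2. Of 23 cell wall integrity genes, 2 were higher, PIR3 and SPI1 at 1.68 (1.51 to 1.87), and 0 were lower, and the median was 0.32 at percentile 99.99. By sign, 20 log2 ratios lay above 0 and 3 below. Those 3, chosen after their values were seen, were PRM5 at 0.760 (0.690 to 0.836), SLT2 at 0.922 (0.865 to 0.982) and YKL161C at 0.933 (0.819 to 1.06). SPI1 is on the stress list too. Of 20 heat shock chaperone genes, HSP26 alone was higher and 0 were lower, HSP10 was at 0.723 (0.674 to 0.774), and the median of 0.01 lay inside the random range at percentile 34.1.

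Genes of respiration had higher medians in the tra1-L3733A library. Of 29 nuclear genes for the respiratory chain and ATP synthase, 5 were higher and 0 lower, with a median of 0.31 at percentile 100. QCR6, of the cytochrome bc1 complex, was at 1.88 (1.77 to 2.00), and the ATP synthase genes ATP7, ATP2 and ATP15 were at 1.85 (1.75 to 1.95), 1.61 (1.58 to 1.63) and 1.63 (1.47 to 1.80). COX4, chosen after its values were seen as the other higher gene of the list, was at 1.54 (1.46 to 1.63), a call lost with scaling by total counts or lane reads. Of 14 TCA cycle genes 0 passed the size rule, and the median was 0.31 at percentile 100. ACO1 was at 1.47 (1.44 to 1.51) and CIT1 at 1.11 (1.07 to 1.15). Of 17 glycolysis and fermentation genes 0 passed the size rule, and the median of 0.24 at percentile 97.6 lay inside the central 95% with the length or GC trend removed (91.2 and 78.1), with no read filter or the 100-read filter (97.4 and 96.9), and without overlapping or unmatched ORFs (97.4). PDC1 was at 1.32 (1.31 to 1.33) and TDH3 at 1.29 (1.281 to 1.295). For either gene the intervals of forward and of reverse reads did not overlap, so the intervals given are too narrow.

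Of 20 nitrogen catabolite repressed genes, 5 were higher and 0 lower, with a median of 0.19 at percentile 99.4. The proline permease PUT4 was at 1.96 (1.83 to 2.10), the ammonium permease MEP2 at 2.08 (1.82 to 2.38), the urea transporter DUR3 at 1.91 (1.60 to 2.29) and the general amino acid permease GAP1 at 1.65 (1.53 to 1.77). DAL3, chosen after its values were seen, was the other higher gene, at 1.58 (1.19 to 2.11) on 91 and 116 reads, a call lost with scaling by total counts or lane reads, which left 4 higher. It was also lost with the GC trend removed, where UGA4, likewise chosen, was higher in its place and the count stayed at 5. Of 17 methionine and sulfate genes, MET14 was lower at 0.592 (0.502 to 0.697) and 0 were higher, MET10 was at 1.38 (1.27 to 1.51), and the median was 0.17 at percentile 98.0, which lay inside the central 95% at 95.8 with the length trend removed and 91.9 with the GC trend removed, and at 97.1 without overlapping or unmatched ORFs. Of 4 alpha-cell specific genes, 3 were higher and 0 lower, with a median of 0.71 at percentile 99.9. The alpha factor gene MF(ALPHA)1 had 32 and 84 reads and a ratio of 3.26 (2.15 to 5.06), SAG1 was at 1.64 (1.46 to 1.84) and STE3, which overlaps YKL177W, at 1.63 (1.17 to 2.26). SAG1 had 521 and 689 reads and STE3 had 68 and 89. The a-cell specific gene STE2 had 3485 and 3008, so the alpha-cell ratios compare low signals. These 8 lists above and 4 below the central 95% made 12 of 37. The sign of these 12 medians was the same with scaling by total counts, lane reads and DESeq2 size factors. Scaling moves all genes alike, so it cannot change a percentile.

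**Figure D3:**
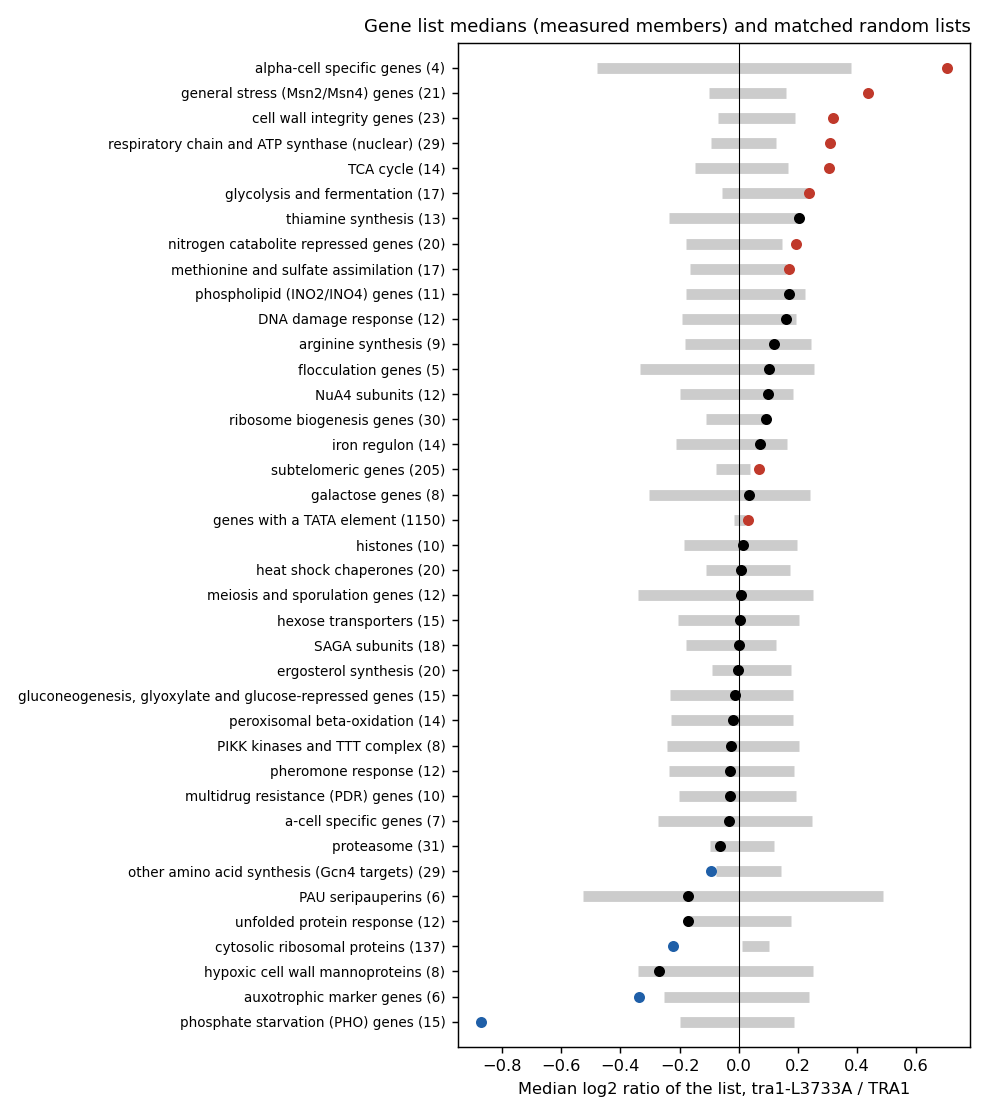
Median log2 ratio of tra1-L3733A to TRA1 for the 37 gene lists, genes with a TATA element and subtelomeric genes, with measured members in parentheses, against the central 95% of 10000 matched random lists (gray bars). Red medians lie above and blue medians below that range; the phosphate starvation list is lowest, at -0.87, and the alpha-cell specific list highest, at 0.71.

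The other 25 lists, the heat shock chaperones among them, lay inside the central 95%. The genes for proteins that share complexes with Tra1 were such lists. Of 18 SAGA genes 0 passed the size rule, with a median of 0.00 at percentile 61.7, TAF5 at 1.06 (0.980 to 1.14) and SPT7 at 0.701 (0.634 to 0.774). Of 12 NuA4 genes 0 passed, with a median of 0.10 at percentile 84.6, ACT1, the actin gene, at 1.28 (1.264 to 1.299) and EAF1, which overlaps OPI7, at 1.05 (0.969 to 1.15). The forward and reverse intervals of ACT1 did not overlap, so its interval is too narrow. With scaling by total counts or lane reads, 1 SAGA gene (SPT7) and 1 NuA4 gene (EAF6, chosen after its values were seen) were lower, and with the GC trend removed 1 NuA4 gene (ESA1, likewise chosen) was higher. The 8 genes of other PIKK kinases and the TTT complex had a median of -0.02 at percentile 41.5, with 0 passing, TOR2 at 1.11 (1.04 to 1.18) and TOR1 at 0.812 (0.746 to 0.883).

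Among lists of carbon use inside the range, 15 measured hexose transporter genes had 2 higher, HXT4 at 1.70 (1.65 to 1.75) and HXT3 with an interval of 1.469 to 1.532, and 2 lower, HXT13 at 0.549 (0.386 to 0.773) and HXT8 at 0.600 (0.446 to 0.800), with a median of 0.01 at percentile 52.5, and similar copies make these values uncertain. The HXT3 call was lost, and the split was 1 higher and 3 lower, with scaling by total counts or lane reads and with the length trend removed. With no read filter the list's median was 0.17 at percentile 95.3, still inside the central 95%. Of 8 galactose genes, GCY1, which overlaps YOR121C, was higher at 1.70 (1.58 to 1.84) and 0 were lower, with a median of 0.04 at percentile 65.4 and PGM2 at 1.28 (1.22 to 1.33). For 15 genes of gluconeogenesis and glucose repression the median was -0.01 at percentile 49.3 with 0 passing, ADH2 at 1.05 (1.02 to 1.07) and MDH2 at 1.32 (1.24 to 1.41). For 14 genes of peroxisomal beta-oxidation it was -0.02 at percentile 50.1 with 0 passing, TES1, which overlaps YJR020W, at 1.42 (1.24 to 1.61) and PEX11 at 0.982 (0.851 to 1.13).

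Among lists of synthesis pathways inside the range, 9 arginine genes had a median of 0.12 at percentile 78.7 with 0 passing, ARG1 with an interval of 0.973 to 1.03 and CPA1 at 1.19 (1.15 to 1.23). Of 11 phospholipid genes, CHO2 at 1.54 (1.48 to 1.60) and INO1 at 1.60 (1.29 to 1.98) were higher and 0 lower, with a median of 0.17 at percentile 91.5, and 0 passed with scaling by total counts. Of 20 ergosterol genes 0 passed, with a median of -0.00 at percentile 22.6, ERG11 at 1.11 (1.08 to 1.14) and ERG25 at 1.06 (1.03 to 1.09), and with scaling by total counts 1 gene (ERG26, chosen after its values were seen) was lower. Of 14 iron regulon genes, ENB1 was lower at 0.607 (0.530 to 0.696) and 0 were higher, with a median of 0.07 at percentile 82.3 and FRE3 at 0.700 (0.543 to 0.899), which passed as lower with scaling by total counts or lane reads. Of 13 thiamine genes, THI7 at 1.60 (1.51 to 1.71) and THI11, which has near-identical copies, at 1.58 (1.19 to 2.09) were higher and 0 lower, with a median of 0.20 at percentile 97.1. The list lay above the central 95%, at 98.3, with the GC trend removed, and 0 genes passed with scaling by total counts.

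Of 30 ribosome biogenesis genes, EBP2 was lower at 0.667 (0.606 to 0.733), a call lost with DESeq2 size factors or the GC trend removed, and 0 were higher, with a median of 0.09 at percentile 95.8 and RLP7 at 1.32 (1.18 to 1.48). Of 31 proteasome genes, PRE9 was lower at 0.666 (0.626 to 0.708), a call lost with the length or GC trend removed, and 0 were higher, with a median of -0.06 at percentile 8.28 and RPT2 at 0.681 (0.640 to 0.725), which passed as lower with scaling by total counts or lane reads. Of 12 unfolded protein response genes 0 passed, with a median of -0.17 at percentile 2.79, which moved to 1.03 with the GC trend removed, PDI1, which overlaps YCL041C, at 1.06 (1.04 to 1.08) and KAR2 at 0.960 (0.933 to 0.987). Of 12 DNA damage genes, the ribonucleotide reductase gene RNR4 was higher at 1.56 (1.51 to 1.60), a call lost with scaling by total counts or lane reads, and 0 were lower, with a median of 0.16 at percentile 94.4 and RNR1 at 1.49 (1.44 to 1.55), which passed as higher with the length or GC trend removed. With the 100-read filter that list lay above the central 95%, at 98.9. The 10 histone genes had a median of 0.02 at percentile 46.9 with 0 passing, HHT2 at 1.05 (1.01 to 1.09) and HHT1 at 0.974 (0.935 to 1.02). The 10 multidrug resistance genes had a median of -0.03 at percentile 35.2 with 0 passing, the drug pump genes PDR5 at 0.943 (0.922 to 0.965) and SNQ2 at 0.712 (0.679 to 0.746), which passed as lower with scaling by total counts.

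Among lists of mating, meiosis and the cell surface, 12 measured pheromone response genes had a median of -0.03 at percentile 44.9, with STE12 at 0.580 (0.516 to 0.651) and PRM3 at 0.621 (0.383 to 0.985) lower and 0 higher. The 7 a-cell specific genes had a median of -0.03 at percentile 38.7 with 0 passing, STE6 at 0.977 (0.935 to 1.02) and STE2 at 1.07 (1.02 to 1.13). STE2 had 3485 and 3008 reads, against 68 and 89 for STE3. Of 12 meiosis genes, IME1 was higher at 2.05 (1.40 to 3.03) and SPS1 lower at 0.602 (0.385 to 0.926), with a median of 0.01 at percentile 65.9. On reverse reads alone IME1 was at 1.47 (0.854 to 2.55) and SPS1 at 0.767 (0.423 to 1.36), so neither passed. The 8 hypoxic mannoprotein genes had a median of -0.27 at percentile 6.51 with 0 passing, DAN4 at 0.791 (0.698 to 0.896) and TIR3 at 1.22 (1.06 to 1.41). With the GC trend removed the percentile was 1.95 and 1 gene (TIR4, chosen after its values were seen) was lower. Of 22 PAU genes 6 had enough reads, and they had a median of -0.17 at percentile 29.0 with 0 passing, PAU2 at 1.08 (0.663 to 1.76) and PAU5 at 0.722 (0.422 to 1.21). With no read filter the PAU median was 0.04 at percentile 52.7, so its sign depended on the filter. The 5 flocculation genes had a median of 0.10 at percentile 81.4 with 0 passing, FLO1 at 1.39 (1.28 to 1.53) and FLO5 at 1.07 (0.972 to 1.19). PAU and FLO genes are similar in sequence, so their values are uncertain.

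Genes with a TATA element were measured as a class because SAGA is known for its role at such promoters. Of 1150 measured genes with the element, 66 were higher and 76 lower, and the median log2 ratio of 0.03 lay at percentile 99.84 of matched random lists, whose central 95% ran from -0.01 to 0.02. Among all 6248 tested ORFs, 175 (2.80%) were higher and 341 (5.46%) lower. With scaling by total counts 37 were higher and 107 lower, with a median of -0.07, and with lane reads 40 were higher and 105 lower, with a median of -0.06, so the sign of the median depended on the scaling. Among all tested ORFs, 91 were higher and 515 lower with total counts. The percentile stayed at 99.84 with either scaling, since scaling moves all genes alike. With the GC trend removed 54 were higher and 77 lower, and the percentile was 95.88, inside the central 95%. Of 205 measured genes within 20 kb of a chromosome end, 19 were higher and 19 lower, with a median of 0.07 at percentile 99.96 against -0.08 to 0.04. With scaling by total counts 7 were higher and 27 lower, with a median of -0.03, and with lane reads 7 were higher and 26 lower, with a median of -0.02. The percentile stayed at 99.96 with either scaling. With the GC trend removed 12 were higher and 18 lower. Without overlapping or unmatched ORFs, an alternative chosen after seeing the data, 9 were higher and 18 lower, and the percentile was 97.23, inside the central 95%.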

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

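The counts of 1 read direction and the removal of overlapping or unmatched ORFs were chosen after seeing the data. No paired analysis was possible because each strain had 1 library, and for the same reason no library could be left out. The TRA1 count ratio of tra1-L3733A to TRA1, 0.526 as reported, was 0.492 with total-count scaling, 0.495 with lane-read scaling, 0.507 on forward reads and 0.544 on reverse reads, and stayed below 1 in each. The number of higher ORFs, 175 as reported, was 91 with total-count scaling, 98 with lane-read scaling, 20 with the 2-fold size rule and 502 with the 1.3-fold rule. The number of lower ORFs, 341 as reported, was 515 with total-count scaling, 57 with the 2-fold rule and 731 with the 1.3-fold rule. These shifts follow from the construction of each setting: total-count scaling moves every log2 ratio by -0.098 and lane-read scaling by -0.0896. The same shift turned the sign of the TATA class median to -0.065 and -0.0566, and of the subtelomeric median to -0.0281 and -0.0197, by construction. With the GC trend removed the TATA median was 0.0198, inside the central 95%, and without overlapping or unmatched ORFs the subtelomeric median was 0.0295, inside it too. The cause of either was not tested. The number of lists outside the central 95%, 12 as reported, was 10 to 12 over the 5 alternatives that can change it, and 9 to 11 of the reported lists kept their side. Scaling moves every gene alike and cannot change a percentile, so it tests nothing there. The thiamine list lay above it with no read filter, with the 100-read filter, with the GC trend removed and without overlapping or unmatched ORFs. The alpha-cell list had too few genes for a median with the 100-read filter and without overlapping ORFs. On forward reads DDR2 was at 0.987, and the cause was not tested. The other 24 of the 25 ORFs named first, TRA1 included, kept their direction under every alternative that gave them a value. TRA1 and PUT4 missed the 2-fold rule. Among all named genes, 8 calls were lost on reverse reads (EBP2, HXT3, HXT8, HXT13, ATP15, PRM3, IME1 and SPS1) and 2 on forward reads (CHO2 and PRE9), beside DDR2. PRM3 and SPS1 also missed the rule with the assumed coefficient of variation of 0.1. PHM6 had too few reads for the 100-read filter and the reverse reads. Depth limits genes such as PHM6, with 33 and 3 reads, and the PAU family, of which 6 of 22 genes had 20 reads.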

Other observations

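The tests of PHO4 and PHO2 mRNA, of other culture differences, of growth, of long genes and of the TRA1 neighbourhood, and the genes and gene groups in the next paragraph, were chosen after the results were seen.

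Genes of lysine synthesis were lower in the tra1-L3733A library in 7 of 9 cases. Beside LYS1, LYS9, LYS20 and LYS2 these were LYS4 at 0.623 (0.578 to 0.672), LYS12 at 0.605 (0.566 to 0.647) and LYS21 at 0.652 (0.612 to 0.695), while LYS5 was at 1.12 (0.914 to 1.37) and LYS14, which encodes the activator of the pathway, at 0.860 (0.748 to 0.989). Of 10 genes of leucine and branched-chain amino acid synthesis or known as targets of Leu3, 4 were lower: LEU1, OAC1, LEU9 at 0.597 (0.553 to 0.644) and BAT1 at 0.585 (0.568 to 0.603). LEU4 was at 0.761 (0.740 to 0.783), ILV2 at 0.693 (0.672 to 0.714), LEU2 at 1.10 (1.01 to 1.20) and GDH1 at 1.29 (1.27 to 1.32). Of 7 copper genes 4 were lower, CUP1-1 at 0.496 (0.464 to 0.529), CUP1-2, the copper chaperone CCS1 at 0.523 (0.479 to 0.572) and COX17, a copper chaperone for cytochrome oxidase, at 0.467 (0.372 to 0.583), while the superoxide dismutase SOD1 was at 1.20 (1.18 to 1.23), the copper transporter CTR1 at 0.815 (0.687 to 0.965) and CRS5 at 0.673 (0.480 to 0.935). PHO5, the main secreted acid phosphatase, was at 0.475 (0.444 to 0.508), on 3103 and 1187 reads. Of 5 other phosphate genes outside the list (PHO3, PHO86, PHO87, PHO90 and PHO91) 0 passed the size rule, and their median log2 ratio was -0.15. The mating type gene MATALPHA1, with 3 and 4 reads, was below the read minimum.

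Phosphate starvation genes were lower as a group. Removing the trends with length and then GC left a median log2 ratio of -0.883 at percentile 0.0, which argues against such a bias as the whole cause. Lower mRNA of the activators PHO4 and PHO2 is argued against by their ratios of 0.966 (0.853 to 1.09) and 0.882 (0.762 to 1.02). PHO81, a further regulator that is itself on the list, was lower, at 0.579 (0.529 to 0.633), and was chosen after its values were seen. A part of lower PHO81 mRNA was therefore not excluded. The negative regulators PHO80, at 1.41 (1.09 to 1.81), and PHO85, at 1.14 (1.04 to 1.25), did not pass the size rule but had intervals above 1, so a part of theirs was not excluded. A difference between the cultures other than the allele, such as the phosphate left in the medium, cannot be told apart from the allele with 1 library per strain, and an effect of the allele remains a hypothesis.

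Ribosomal protein genes were lower as a group, with a median of -0.187 at percentile 0.0 after removal of the length and GC trends. Without that removal the median was -0.221, and reads split between copies do not account for the whole of it. The 19 genes without an A or B copy had a median of -0.173 at percentile 0.04, also without that removal, with 12 log2 ratios below 0 and 7 above. They held 1 of the 23 lower calls, however, and the 118 genes with a copy held 22, the 4 named genes among them, so for single genes of a pair the split of reads stays open. The ribosome biogenesis list was not lower, with a median of 0.094 at percentile 95.79. That argues against slower growth of a kind that lowers these genes together with ribosomal protein genes. The difference of the list medians was 0.315 (bootstrap 95% interval over genes 0.107 to 0.387), with the biogenesis list higher. It decides nothing by itself, since it would also be positive if both lists had fallen unequally, and both medians were known when it was computed. Other differences in growth stay open, since the general stress list, which often goes with slow growth, was higher, at a median of 0.44, and so does the culture difference named for the phosphate genes.

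TRA1 mRNA was lower. A bias against long genes is argued against, since the 100 longest other tested ORFs had a median log2 ratio of 0.0035 and TRA1 lay at percentile 1.0 among them. Lower dosage of the chromosome segment is argued against by the 10 nearest tested ORFs, with a median of 0.155, of which 10 lay above the lower limit of the size rule. Their log2 ratios ran from -0.15 to 1.43, and the cause of the highest was not tested. How the tra1-L3733A allele was introduced into the strain is not given in the sources used here, so a different copy number or promoter of the allele itself was not tested.

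Over 5136 ORFs with at least 50 reads per direction and library, forward and reverse log ratios differed with 1.40 times the counting-error variance. Adding that spread would make intervals 1.18 times as wide for these ORFs as a set. The factor is too small for ACT1, PDC1, TDH3 and DDR2, whose forward and reverse intervals did not overlap. For ACT1 the forward ratio of 1.238 and the reverse ratio of 1.327 both lay outside its interval of 1.264 to 1.299. The same held for other named genes, among them TRA1, at 0.5073 and 0.544 against 0.5092 to 0.5438. HSP26 was at 2.74 and 2.912 against 2.742 to 2.905, and PIR3 at 2.637 and 2.467 against 2.492 to 2.621. For TRA1, HSP26 and PIR3 the forward and reverse intervals overlapped.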
